A study of Mus musculus with 30 samples.

How the data were processed

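Chromatin immunoprecipitation followed by sequencing had been carried out on micrococcal nuclease-digested chromatin of mouse bone marrow-derived macrophages, primary phagocytes grown from bone marrow of C57BL/6 mice with L929-conditioned medium and used on day 7 of differentiation. Per the labels, cells were left untreated or were treated with lipopolysaccharide (LPS, a bacterial cell wall component that activates macrophages) at 10 ng/ml for 30 min, 1 h, 2 h or 4 h. The precipitated marks were histone H3 acetylated at lysine 27 (H3K27ac), monomethylated at lysine 4 (H3K4me1) and trimethylated at lysine 4 (H3K4me3). Each mark and condition had 2 samples, giving 30 samples, and each sample came with its own list of peaks, so peaks had been called per sample and not on pooled samples. The labels do not say whether the 2 samples of a condition came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

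Per the submitters' processing notes, Bowtie 0.12.7, MACS 1.4 and the mouse genome build mm9 were used. The control sample of the peak calls, read filters and the number of reads were not given in the sources used here. The score of each peak is the authors' deposited value, which MACS 1.4 writes as -10 times the log10 of the peak's p-value; the lowest score was 50. Scores were used here only to rank or filter peaks within a list. With no read counts the depth of each sample is unknown, and no interval that needs it is given. The highest peak end on chromosome 1 was 197068972, and all coordinates are mm9 coordinates counted from 1.

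For each mark, the peaks of the 10 lists were merged where they overlapped or touched, giving union regions, and a region was counted as called in a list when a peak of the list overlapped it by 1 bp or more. A region was gained at a time point when it was called in both LPS lists and in neither untreated list, and lost when it was called in both untreated lists and in neither LPS list. Each such count was set beside the 4 other patterns in which the same 4 lists divide into 2 with and 2 without a call. With 2 samples against 2, the smallest two-sided p an exact test allows is 0.333, so these counts carry no p-value. Means over time points are given with the SD over the 4 time points, which share the untreated lists.

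Peaks per list, covered bases and median peak width were compared between the 2 untreated and 8 LPS lists of a mark with an exact permutation test over all 45 splits (two-sided), and between the 5 conditions with an exact test of the F statistic over all ways to divide 10 lists into 5 pairs. The Jaccard index, the bases covered by both of 2 lists over the bases covered by either, was averaged over the 5 replicate pairs and compared with all such pairings (exact, one-sided). Since every replicate pair joins a replicate 1 with a replicate 2 list, it was also compared with the 120 pairings across numbers; this test was added after the data had been seen. Benjamini-Hochberg adjustment covered 9 tests for list measures and 3 for the Jaccard index. The number of regions called in all 8 LPS lists and in neither untreated list, and the reverse, was compared with the same number for every other pair of lists (45 pairs, exact, one-sided, 6 tests); this result was chosen after the data had been seen. The overlap of gains between time points was set beside 100 simulations in which, per region and replicate number, the calls of the 5 conditions were shuffled, so that the simulated comparisons shared their untreated lists as the real ones do, and beside the overlap of independent lists.

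H3K4me1 regions called in both untreated lists and overlapping no H3K4me3 peak of either untreated list were taken as distal; those also without any H3K27ac peak in either untreated list are called H3K4me1-only. The background for H3K27ac gained there is the percent with H3K27ac in both untreated lists among the distal regions without it in either LPS list. Width-matched percentages were averaged over width classes weighted as in the gained regions. Named regions followed a fixed rule: for each mark, the 5 regions gained and the 5 lost at the most time points both in the deposited lists and in lists reduced to equal length, with ties broken by the mean within-list percentile of the best peak score. The tests, this rule and most alternatives were chosen before the data were examined. The alternatives among these were lists of equal length, scores of 100 or more, an overlap of 50%, windows of 1 kb, peaks stitched over gaps of up to 1 kb, leaving out each replicate and a replicate block. All of them were applied to the counts of gained and lost regions. Peaks per list had scores, leaving out each replicate and the block. Shares of regions had equal length, scores, the overlap of 50% and leaving out each replicate. The Jaccard index had equal length and scores only. Lists reduced to equal covered bases, by taking the highest scoring peaks and the widest among tied scores, and autosomes only were added after the data had been seen. So were all alternatives for covered bases and median peak width, leaving out lists for the Jaccard index, the width matching, the reverse share by LPS lists and the chromosome shares.

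The gene list and motif tests planned for an mm9 annotation and genome were not run, because neither was used here; regions are therefore given by position without a gene, exon or intron. The region counts were tested on simulated lists made from the untreated replicate 1 list of each mark with 95% of peaks kept at random and 200 regions planted as gained and 200 as lost: the lowest number recovered as gained was 177 for H3K27ac, 175 for H3K4me1 and 171 for H3K4me3. This tests the counting and not the sensitivity in the real lists. Their replicate pairs differed more, with Jaccard indices of 0.330 to 0.754. The H3K4me3 gains at 4 h counted with bedtools 2.31.1 came to the same 813 of 72760 regions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.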

Results

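Peaks of 3 histone marks were available for macrophages without LPS and after 30 min, 1 h, 2 h and 4 h with LPS, with 2 lists per mark and condition. H3K27ac is a mark of active enhancers and promoters, H3K4me1 is found mostly at enhancers and H3K4me3 at active promoters. The lists held 79322 to 259773 peaks for H3K27ac, 102819 to 210037 for H3K4me1 and 30038 to 45461 for H3K4me3. The design asks which regions carry each mark before and at each time after LPS, and whether regions that acquire acetylation already carried H3K4me1.

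H3K27ac peaks numbered 95187.5 ± 22437 (SD, n = 2) in untreated macrophages and 173034 ± 46319 (SD, n = 8) with LPS, and all 8 LPS lists were longer than both untreated lists. The bases under H3K27ac peaks came to 233 ± 29.1 Mb (SD, n = 2) and 238 ± 49.1 Mb (SD, n = 8), and the median peak width to 1279 ± 417 bp (SD, n = 2) and 870 ± 223 bp (SD, n = 8). H3K4me1 peaks numbered 109308 ± 9176 (SD, n = 2) and 147124 ± 34718 (SD, n = 8), and H3K4me3 peaks 38054.5 ± 7797 (SD, n = 2) and 39309 ± 5798 (SD, n = 8). None of these differences in peak number passed the exact permutation test, with p = 0.0889 for H3K27ac, 0.111 for H3K4me1 and 0.889 for H3K4me3 (adjusted p = 0.25, 0.25 and 0.889); the smallest p that the 45 splits allow is 0.0222. At scores of 100 or more the unadjusted exact p for H3K27ac was 0.0444, for a difference of 29163.5 peaks against 77846 in all lists. The H3K4me3 difference of 1254.38 peaks turned to -3447 at these scores and to -4259.12 without untreated replicate 1. The median H3K4me3 peak width was 894 ± 96.7 bp (SD, n = 8) with LPS and 1117 ± 137 bp (SD, n = 2) without, a difference with an exact p of 0.0444 that did not hold after adjustment (0.25) and whose unadjusted p was above 0.05 in 7 of 12 alternatives. Between the 5 conditions, the lowest exact p of the F statistic over the 3 marks and these measures was 0.266 (adjusted p = 0.954).

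**Figure D1:**
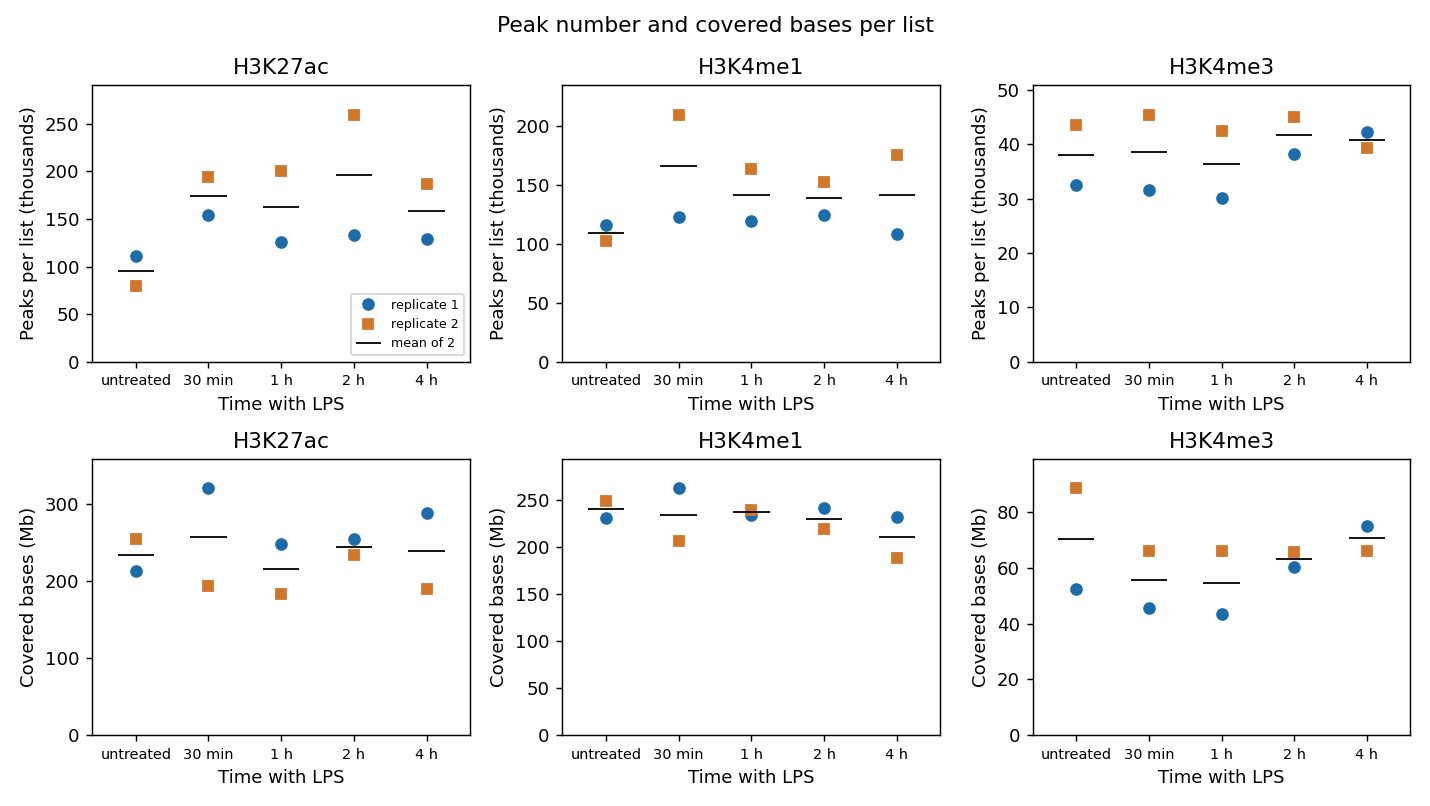
Number of peaks (top, axis in units of 1000) and covered bases in Mb (bottom) of each list by time with LPS, for 3 marks; circles are replicate 1, squares replicate 2 and lines the mean of 2 lists. The LPS replicate 2 lists of H3K27ac hold 186915 to 259773 peaks and those of replicate 1 hold 125313 to 154637.

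The LPS replicate 2 lists of H3K27ac and H3K4me1 stood apart from the other lists of these marks. For H3K27ac they held 210378 ± 33411 peaks (SD, n = 4) with a median width of 663 ± 17.5 bp, against 135689 ± 13069 peaks and 1077 ± 38.8 bp (SD, n = 4) in the LPS replicate 1 lists. Chromosome X carried 0.452% to 0.678% of their H3K27ac peaks, against 1.26% to 1.82% in the LPS replicate 1 lists and 1.78% to 2.61% in untreated lists. For H3K4me1 the same shares were 0.440% to 0.721%, 2.41% to 2.47% and 2.55% to 2.84%. For H3K4me3 they lay closer, at 1.54% to 1.87%, 1.94% to 2.52% and 2.42% to 2.48%, and the list that covered most was untreated replicate 2 with 88.3 Mb. All 30 lists held peaks on chromosome Y.

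Averaged over conditions, the H3K27ac lists of a condition shared more bases than lists of different conditions when replicate 1 lists were set only against replicate 2 lists, but this did not hold for each time point. The mean Jaccard index within conditions was 0.492 ± 0.131 (SD, n = 5 pairs) for H3K27ac, 0.574 ± 0.123 for H3K4me1 and 0.592 ± 0.0448 for H3K4me3, against 0.435, 0.565 and 0.589 for lists differing in condition and number. The exact p over the 120 pairings across numbers was 0.00833, 0.0333 and 0.317 (adjusted p = 0.025, 0.05 and 0.317), and 0.00833 is the smallest they allow. The untreated H3K27ac pair, at 0.695, was the highest of the 5. Of the 6 indices that join a list of the pair with a list of the other number at another LPS time, 1 was above the pair at 30 min (0.481), 2 at 1 h (0.459), all 6 at 2 h (0.330) and 0 at 4 h (0.497). Among LPS lists only, the H3K27ac means were 0.442 and 0.419 (exact p = 0.0417, the smallest that 24 pairings allow, adjusted p = 0.125), and for H3K4me1 and H3K4me3 the exact p was 0.167. The test chosen before, over all divisions of the 10 lists into pairs whatever their number, gave exact p = 0.197, 0.688 and 0.872 (adjusted p = 0.590, 0.872 and 0.872). Lists with the same replicate number were closer across time points, with means of 0.630, 0.801 and 0.647 among the LPS replicate 1 lists and 0.440, 0.538 and 0.728 among the LPS replicate 2 lists, than LPS lists of different number and time, at 0.419, 0.526 and 0.599. The untreated pair had an index of 0.754 for H3K4me1 and 0.538 for H3K4me3.

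In the deposited lists, counted at an overlap of 1 bp, H3K27ac was gained at more regions than it was lost at every time point. Gained regions numbered 16667 at 30 min, 10889 at 1 h, 14576 at 2 h and 15257 at 4 h, a mean of 14347 ± 2464 (SD, n = 4 time points). Lost regions numbered 2642, 5391, 5696 and 5801, a mean of 4882.5 ± 1504. Gains exceeded the highest of the 4 other call patterns (3517, 2432, 2963 and 2931 regions) at all 4 time points and losses at 3 of them. The gained regions covered 38.1 Mb at 30 min, 30.99 Mb at 1 h, 38.5 Mb at 2 h and 39.2 Mb at 4 h. The ratio of gains to losses, 2.94 in the deposited lists, was 2.55 at equal covered bases (means of 4559.75 and 1784.75) and turned to 0.496 in lists of equal length (3637.75 and 7339.75). With an overlap of 50% the ratio was 1.05 and gains were fewer than losses at 1 h (5609 and 9108) and 2 h (7795 and 9473), and at scores of 100 or more it was 1.29 and gains were fewer at 1 h (4618 and 5538). Losses rose to 9094.25 without untreated replicate 2, 13233 without untreated replicate 1 and 10480.5 without LPS replicate 1, and gains to 59658.5 without LPS replicate 1 and 33084 without LPS replicate 2, each of which asks for a call or its absence in fewer lists.

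**Figure D2:**
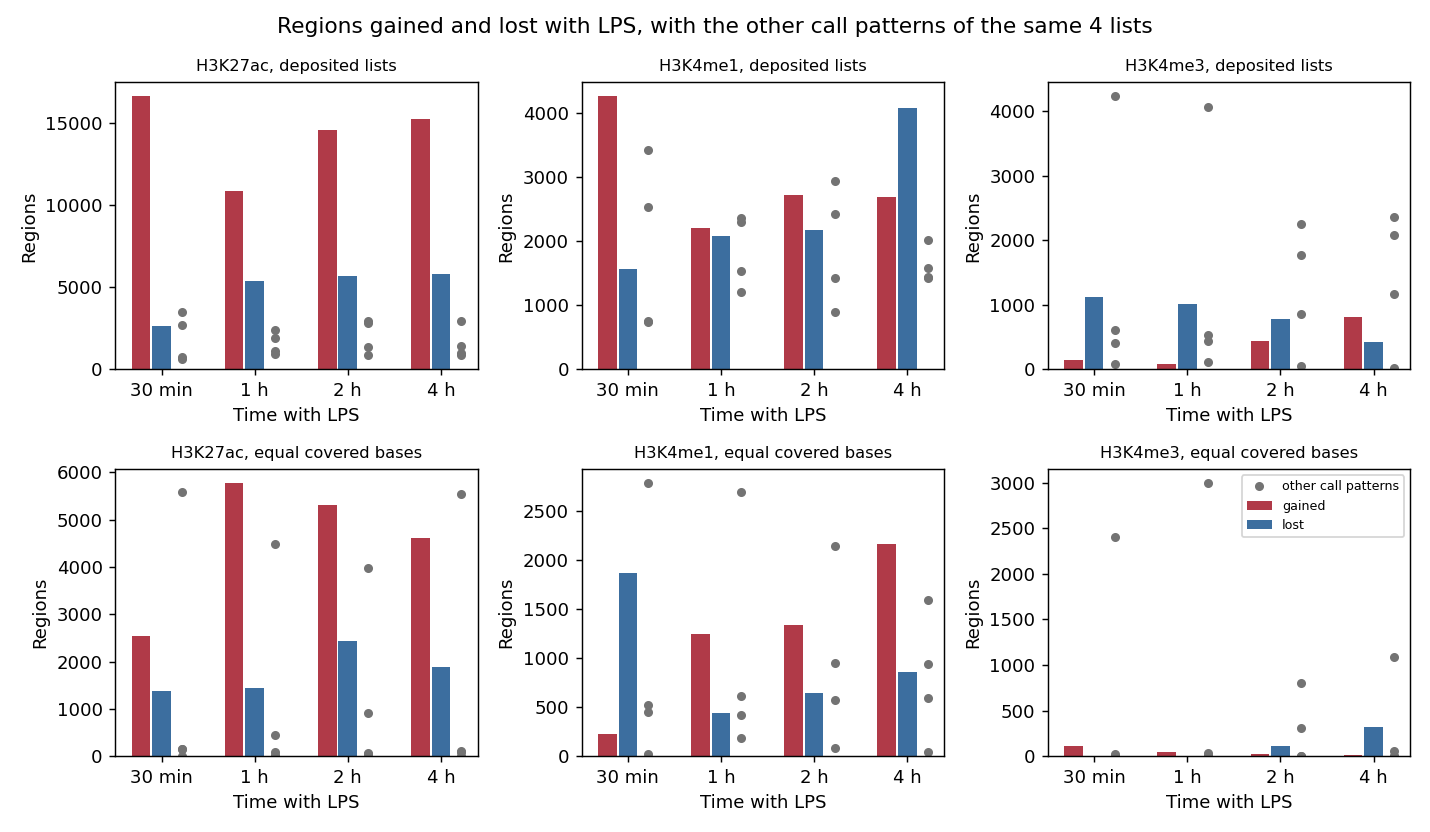
Regions gained (red) and lost (blue) at each time with LPS for 3 marks, in the deposited lists (top) and at equal covered bases (bottom); grey points are the 4 other patterns in which the same 4 lists divide into 2 with and 2 without a call, and each panel has its own scale; the H3K4me3 panel at equal covered bases rests on a choice among tied scores. H3K27ac gains lie above all grey points at 4 of 4 time points in the deposited lists and at 2 of 4 at equal covered bases.

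A set of 2762 H3K27ac regions was called in all 8 LPS lists and in neither untreated list. The next highest count for any other pair of lists standing in place of the untreated pair was 532, so the exact p was 0.0222, the smallest that 45 pairs allow, and 0.133 after adjustment over 6 tests. At equal covered bases 804 regions met the criterion, with 551 for the next pair (exact p = 0.0222), and in lists of equal length 542 did, with 3 of the 45 pairs as high (exact p = 0.0667). Equal covered bases cut the untreated lists at scores of 129 and 1417 and the LPS replicate 2 lists at 50 to 82.1. Untreated peaks under these cuts counted as absent, so the 804 may include regions acetylated before LPS. Equal length cut the untreated lists at 87.0 and 50 and the LPS lists at 108 to 162, which runs the other way. The reverse set, called in both untreated lists and none of the 8 LPS lists, held 1352 H3K27ac regions, and 7 of 45 pairs gave as many (exact p = 0.156). The highest of these, 6645 regions, came from the LPS replicate 2 lists at 1 h and 2 h, which stood apart as given above. The 45 pairs take no account of replicate number, for this or the other marks. Such a p-value therefore does not show that losses were absent. In lists of equal length the reverse set held 3083 regions against 2663 for the next pair (exact p = 0.0222), so there the losses and not the gains reached the smallest p. At equal covered bases it held 583 (exact p = 0.178). Chromosome X held 145 of these 1352 regions (10.7%), 3 of the 2762 gained regions and 1.35% of the 23342 regions called in all 10 lists, beside the low X share of the LPS replicate 2 lists given above.

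The H3K27ac gains ranked highest by the fixed rule were wide regions called in all 8 LPS lists. They lay on chromosome 18 from 65452847 to 65503210, on chromosome 16 from 10564684 to 10592632 and from 95985820 to 96004241, on chromosome 11 from 116236313 to 116246157 and on chromosome 1 from 137703722 to 137721694. The region on chromosome 18 was 50364 bp wide, and the best score within it ranged from 804 to 3176 over the LPS lists. The regions on chromosomes 18, 16 and 11 had H3K4me1 in both untreated lists, whereas the region on chromosome 1 had none there and had H3K4me1 in all 8 LPS lists. In total 383 regions were gained at all 4 time points in both the deposited and the equal length lists.

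**Figure D3:**
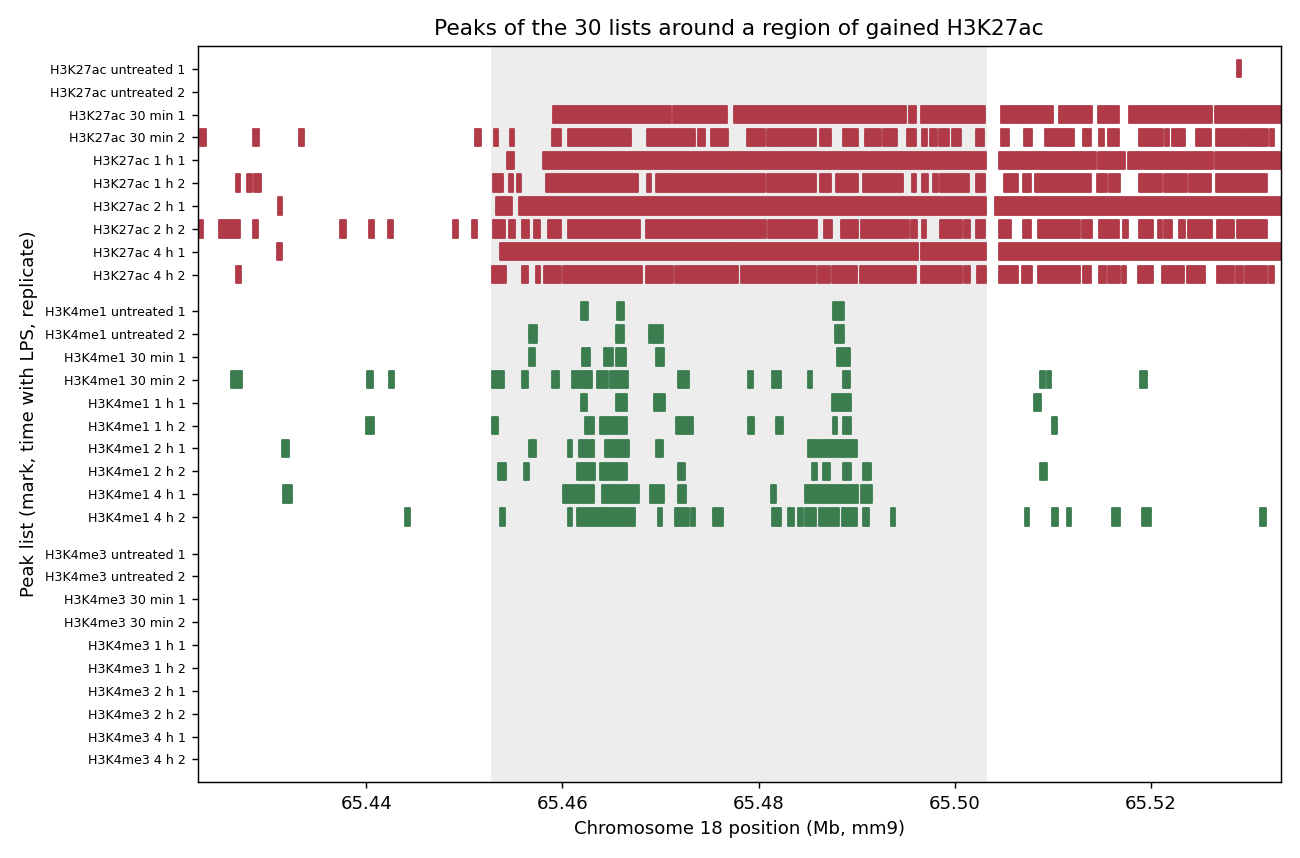
Peaks of the 30 lists around the region gained in H3K27ac on chromosome 18 from 65452847 to 65503210 (shaded; mm9, position in Mb), with a line per list named by mark, time with LPS and replicate. H3K27ac peaks are present in the region in all 8 LPS lists and absent from it in both untreated lists, H3K4me1 peaks are present in all 10 lists and H3K4me3 peaks in none.

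The highest ranked H3K27ac losses kept H3K4me1. They lay on chromosome 12 from 36071764 to 36083735, on chromosome X from 160300997 to 160309477, on chromosome 16 from 81455908 to 81460471 and from 81434031 to 81442226, and on chromosome 4 from 79956278 to 79961013. The region on chromosome 16 from 81455908 had H3K4me1 in 7 of 8 LPS lists and the other 4 in all 8, and all 5 had it in both untreated lists. At all 4 time points in both kinds of list, 632 regions were lost. The 5 ranked regions were not typical of H3K27ac losses in the deposited lists. Averaged over the 4 time points, lost regions had H3K4me1 in both untreated lists at 59.0% and in both LPS lists at 36.1%. Of the 1352 regions called in both untreated lists and none of the 8 LPS lists, 49.5% had H3K4me1 in both untreated lists. H3K4me1 was called in no list at 31.1% of these 1352 regions.

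Most regions gaining H3K27ac met the criterion at 1 time point only, and fewer at all 4. A region missing from 1 of the 2 lists of a time point does not count as gained there. These counts therefore do not show that gains were transient. Of 33636 regions gained at any time, 19212 (57.1%) were gained at 1 time point, 11713 (34.8%) at 30 min or 1 h and not later, 12148 (36.1%) at 2 h or 4 h and not earlier, and 2762 (8.21%) at all 4. Of the 16667 regions gained at 30 min, 32.8% were called in both 4 h lists, 37.1% in neither and the rest in 1 of the 2. Adjacent time points shared 6068 gains between 30 min and 1 h, 5687 between 1 h and 2 h and 7910 between 2 h and 4 h. Simulations with shared untreated lists and no effect gave means of 808, 812 and 812 shared gains and 179 regions gained at all 4 time points (highest 218), and independent lists would share 721, 630 and 883. With 2 untreated lists these could not be divided between time points. The simulations shared them but did not keep their agreement with each other. Part of the excess may therefore still come from the shared controls. The simulations shuffled each replicate number apart. They kept neither the agreement of the 2 lists of a condition nor the number of gains per time point. How much of the sharing follows from LPS therefore cannot be read from them.

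H3K4me1 was gained and lost at similar numbers of regions, a mean of 2974 ± 896 gained and 2477 ± 1105 lost (SD, n = 4 time points). Gains were 4270 at 30 min, 2210 at 1 h, 2727 at 2 h and 2688 at 4 h, above the highest other call pattern (3429, 2369, 2943 and 2026) at 2 of 4 time points, and losses (1564, 2078, 2183 and 4084) were above it at 4 h only. H3K4me1 was called in all 8 LPS lists and neither untreated list at 294 regions, and 6 of 45 pairs gave as many (exact p = 0.133). The highest ranked gains lay on chromosome 12 from 87005130 to 87009348, on chromosome 11 from 100910524 to 100915176, on chromosome 1 from 157587229 to 157590893 and from 137707629 to 137715682, and on chromosome 4 from 62971045 to 62973493. H3K27ac was called in all 8 LPS lists at 4 of these 5 regions, and in untreated lists only at the region on chromosome 12. The highest ranked losses lay on chromosome 13 from 77855608 to 77857705, on chromosome X from 150069757 to 150071006, on chromosome 4 from 44786008 to 44787259, on chromosome 1 from 163767060 to 163768168 and on chromosome 10 from 99046714 to 99048035, with widths of 1109 to 2098 bp. The ratio of gains to losses was 1.20 in the deposited lists, 1.30 at equal covered bases (means of 1243.25 and 954.5) and 0.394 in lists of equal length (1229.25 and 3120). At equal covered bases it was 0.123 at 30 min (230 and 1869), 2.79 at 1 h, 2.10 at 2 h and 2.50 at 4 h. With an overlap of 50% it was 0.758 and at scores of 100 or more 0.637. Without untreated replicate 1, gains rose to 6162.5 and losses to 10551.8, without untreated replicate 2 losses rose to 5184.5, without LPS replicate 1 they were 44224 and 15577.5, and without LPS replicate 2 gains were 7664.25.

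Few regions met the criterion for a gain or a loss of H3K4me3. Gained regions numbered 141 at 30 min, 86 at 1 h, 446 at 2 h and 813 at 4 h, and lost regions 1123, 1016, 783 and 425. Neither exceeded the highest other call pattern (4230, 4063, 2254 and 2353) at any of the 4 time points. Changes of H3K4me3 were thus not resolved from differences between lists, and the low counts do not show that change was small. Of 1093 regions gained at any time, 893 (81.7%) were gained at 2 h or 4 h and not earlier. In lists of equal length gains were 148, 152, 306 and 605. Equal covered bases could not be used for H3K4me3, because in untreated replicate 2 the 7963 peaks kept included 7808 of the 13358 tied at a score of 3100. Mean gains of 371.5 rose to 1634.25 without untreated replicate 2, 7514 without LPS replicate 1 and 3701.75 without LPS replicate 2, and mean losses of 836.75 to 13729.5 without untreated replicate 1, 2737 without untreated replicate 2, 1700 without LPS replicate 1 and 1893.75 without LPS replicate 2.

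The highest ranked H3K4me3 gains lay on chromosome 3 from 57378743 to 57380845, on chromosome 4 from 135803275 to 135805149, on chromosome 1 from 75483683 to 75484863, on chromosome 6 from 85462885 to 85464205 and on chromosome 2 from 38211474 to 38213460. None of these 5 had H3K27ac in untreated lists, and at most 1 of 8 LPS lists had it. The highest ranked losses lay on chromosome 8 from 108527765 to 108530372, on chromosome 1 from 84316783 to 84318811, on chromosome 3 from 49866524 to 49867873, on chromosome 2 from 155229650 to 155233892 and on chromosome 16 from 24669901 to 24671000. These kept H3K27ac in all 8 LPS lists except the region on chromosome 3, which had it in 5. In both kinds of list, 62 regions were lost in H3K4me3 at all 4 time points. Only 19 regions had H3K4me3 in all 8 LPS lists and neither untreated list, and 16 of 45 pairs gave as many (exact p = 0.356).

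H3K27ac appeared with LPS at part of the distal H3K4me1 regions that lacked it, at a mean share close to that of the background. Of 37197 distal H3K4me1 regions in untreated macrophages, 14898 were H3K4me1-only and 15461 had H3K27ac in both untreated lists. H3K27ac appeared in both LPS lists at 2829 H3K4me1-only regions (19.0%) at 30 min, 2062 (13.8%) at 1 h, 2106 (14.1%) at 2 h and 2519 (16.9%) at 4 h, a mean of 16.0% ± 2.44 (SD, n = 4 time points). Of distal H3K4me1 regions without H3K27ac in either LPS list, 8.60%, 16.6%, 20.5% and 18.8% had it in both untreated lists. This background averaged 16.1% ± 5.26 and was above the gaining share at 3 of 4 time points. Both shares are taken among regions with H3K4me1 in untreated lists, which held 59.0% of lost and 20.4% of gained H3K27ac regions. The same background among H3K4me1 regions chosen by the LPS lists in place of the untreated lists is called the reverse share. It was 7.58%, 20.01%, 28.0% and 23.8%, a mean of 19.9% ± 8.81. The gaining share was 5.92% with an overlap of 50% and 9.93% at scores of 100 or more. In lists of equal length it was 6.24% ± 1.14, the background 19.8% ± 4.61 and the reverse share by LPS lists 27.0% ± 8.59. Of the acetylated regions in the deposited lists, 6.12%, 15.8%, 17.7% and 17.8% lost H3K27ac from both LPS lists. Their mean of 14.4% ± 5.57 stands beside the gaining mean of 16.0%. With the LPS replicate 1 and replicate 2 lists taken singly, the share of H3K4me1-only regions with H3K27ac was 36.8% and 27.0% at 30 min. It was 23.6% and 26.3% at 1 h, 25.6% and 33.7% at 2 h and 28.3% and 26.4% at 4 h.

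Most regions gaining H3K27ac had no H3K4me1 peak before LPS, but so did most regions of the other call patterns without a call in untreated replicate 2. H3K4me1 was called in both untreated lists at 20.4% ± 1.90 (SD, n = 4 time points) of gained regions and in neither at 69.5% ± 2.27, and 4.79% ± 1.37 of the latter had H3K4me1 in both LPS lists of the time point. Lost regions had H3K4me1 in both untreated lists at 59.0% ± 2.27 and regions with H3K27ac in all 4 lists at 92.5% ± 1.16. Regions called in all 4 lists were wider (mean of medians 6143 bp) than gained regions (1887 bp), and at matched width 77.6% of them and 63.0% of lost regions had H3K4me1. Regions called in the replicate 1 lists only, or in untreated 1 and LPS 2 only, which share with the gained regions the absence of a call in untreated replicate 2, stood at 31.9% and 26.0% at matched width, and the other 2 patterns at 66.2% and 65.6%. Without width matching, H3K4me1 was in neither untreated list at 60.3% and 64.5% of the former and at 27.5% and 26.7% of the latter. A lack of H3K4me1 is therefore not particular to LPS gains. The share with H3K4me1 among gains was 12.04% with an overlap of 50%, 32.9% without untreated replicate 2 and 11.4% without LPS replicate 1.

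**Figure D4:**
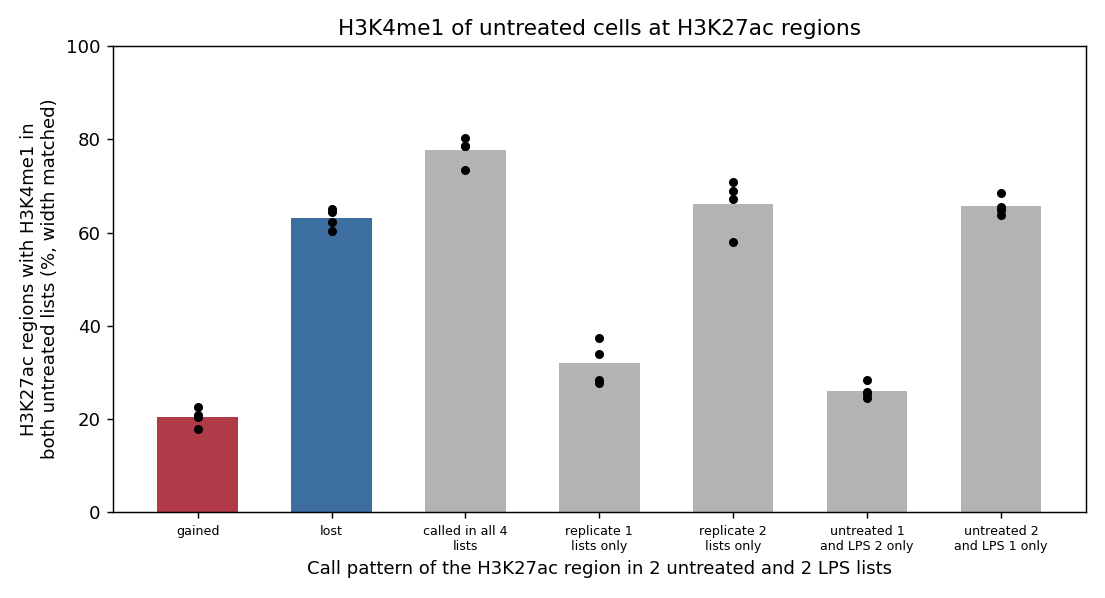
Percent of H3K27ac regions with H3K4me1 in both untreated lists at matched width, by the region's call pattern in 2 untreated and 2 LPS lists; bars are means of 4 time points and points the time points. Gained regions stand at 20.4%, lost regions at 63.0% and regions called in all 4 lists at 77.6%, with the 4 other patterns between 26.0% and 66.2%.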

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

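The equal covered bases and autosomes only settings, every alternative for regions in every LPS list or every untreated list, every alternative for covered bases and median peak width, and leaving out lists or pairing across replicate numbers for the Jaccard index were chosen only after the results were seen. The cause of a move was not tested, except that leaving out a list, a stricter score or fewer bases changes by construction how many lists or peaks can meet a criterion. On autosomes only, all counts stayed within 1.5 times. Of 42 alternatives for the Jaccard index 2 changed its side of the threshold, both with a replicate block, in which replicate 1 lists were paired only with replicate 2 lists: 0.492 for H3K27ac (exact p = 0.00833) and 0.574 for H3K4me1 (exact p = 0.0333). Leaving out either list of a condition removed its whole pair and gave the same value, so the 42 are not all distinct. The index was 0.442 to 0.533 for H3K27ac, 0.529 to 0.614 for H3K4me1 and 0.575 to 0.605 for H3K4me3 when a pair of lists was left out. Among alternatives for counts per time point, covered bases and median widths, 171 kept their call or stayed within 1.5 times and 177 counts moved by more than 1.5 times. Of the others, 5 changed sign and 7 lost their call. The 171 include the counts with a replicate block, which are the same by construction. With no read counts, depth could not be equalised.

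With lists of equal length, gains numbered 3637.75 for H3K27ac and 1229.25 for H3K4me1, and losses numbered 7339.75 for H3K27ac. There, regions in every LPS list and no untreated list numbered 542 for H3K27ac and 114 for H3K4me1, and regions in every untreated list and no LPS list numbered 3083 for H3K27ac (exact p = 0.0222) and 744 for H3K4me1. H3K27ac was gained at 6.24% of H3K4me1-only regions, and 26.5% of gained H3K27ac regions had H3K4me1 in untreated cells. At scores of 100 or more, gains numbered 6153.5 for H3K27ac, 1368.25 for H3K4me1 and 172.25 for H3K4me3, and losses numbered 448 for H3K4me3. Regions in every LPS list and no untreated list numbered 1108 for H3K27ac, 163 for H3K4me1 and 9 for H3K4me3, and regions in every untreated list and no LPS list numbered 79 for H3K4me3. H3K27ac was gained at 9.93% of H3K4me1-only regions. With a 50% overlap, gains numbered 7996.25 for H3K27ac, and losses numbered 7629 for H3K27ac and 3901 for H3K4me1. Regions in every LPS list and no untreated list numbered 691 for H3K27ac, and regions in every untreated list and no LPS list numbered 2403 for H3K27ac. H3K27ac was gained at 5.92% of H3K4me1-only regions, and 12.04% of gained H3K27ac regions had H3K4me1 in untreated cells. In 1 kb windows, gains numbered 51205 for H3K27ac, 10148.5 for H3K4me1 and 1413.75 for H3K4me3, and losses numbered 25902.5 for H3K27ac, 8588.5 for H3K4me1 and 2886.75 for H3K4me3. Windows in every LPS list and no untreated list numbered 12951 for H3K27ac, 1252 for H3K4me1 and 63 for H3K4me3, and regions in every untreated list and no LPS list numbered 5328 for H3K27ac, 1144 for H3K4me1 and 478 for H3K4me3. With peaks stitched over 1 kb, gains numbered 5074 for H3K27ac, 1500 for H3K4me1 and 216.5 for H3K4me3, and losses numbered 1511.75 for H3K27ac and 1224.5 for H3K4me1. Regions in every LPS list and no untreated list numbered 912 for H3K27ac and 166 for H3K4me1, and regions in every untreated list and no LPS list numbered 387 for H3K27ac and 185 for H3K4me1. At equal covered bases, which for H3K4me3 rests on a choice among tied scores in untreated replicate 2, gains numbered 4559.75 for H3K27ac, 1243.25 for H3K4me1 and 48.5 for H3K4me3, and losses numbered 1784.75 for H3K27ac, 954.5 for H3K4me1 and 112.75 for H3K4me3. In those lists, regions in every LPS list and no untreated list numbered 804 for H3K27ac, 98 for H3K4me1 and 0 for H3K4me3, and regions in every untreated list and no LPS list numbered 583 for H3K27ac, 145 for H3K4me1 and 0 for H3K4me3. H3K27ac was gained at 13.5% of H3K4me1-only regions, whose choice uses those H3K4me3 lists.

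Leaving out a replicate gave mean gains of 16876.5 to 59658.5 for H3K27ac, 4210 to 44224 for H3K4me1 and 497.75 to 7514 for H3K4me3, and mean losses of 6849.5 to 13233, 3340.75 to 15577.5 and 1700 to 13729.5. Regions in every remaining LPS list and no untreated list ranged from 2981 to 3963, 323 to 1707 and 19 to 145, and the reverse from 1400 to 6245, 431 to 5176 and 191 to 9391. The H3K27ac value of 3963 without untreated replicate 1, and 3591 without untreated replicate 2, had an exact p of 0.111, the smallest that 9 splits allow. H3K27ac was gained at 15.5% to 28.6% of H3K4me1-only regions, and 11.4% to 32.9% of gained regions had H3K4me1 in untreated cells. The LPS minus untreated difference in peaks per list ranged from 61980.5 to 93711.5 for H3K27ac, 28828.4 to 44304.5 for H3K4me1 and -4259.12 to 6767.88 for H3K4me3, whose main value was 1254.38. At scores of 100 or more the difference was 29163.5 for H3K27ac (exact p = 0.0444) and -3447 for H3K4me3 (exact p = 0.267), a change of sign. The difference in covered bases also changed sign. For H3K27ac it was -21.6 Mb at scores of 100 or more and, against 5.02 Mb in all lists, -15.5 Mb without untreated replicate 1, -6.59 Mb without 30 min replicate 1, -1.95 Mb without 4 h replicate 1 and at most 25.6 Mb without another list. For H3K4me3 it was 8.77 Mb without untreated replicate 2 and -27.4 Mb without untreated replicate 1, against -9.30 Mb. The H3K4me3 median width lost its unadjusted call in 7 of its 12 alternatives, at scores of 100 or more (exact p = 0.444), without either untreated list (0.111 and 0.333, where 0.111 is the smallest possible) and without either 30 min list, 1 h replicate 2 or 4 h replicate 2 (0.0556 each).

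The replicate numbers were not taken to pair untreated with LPS samples, since the correlation of replicate differences between untreated and LPS conditions was -0.0958 to -0.0121 for H3K27ac, -0.0358 to 0.0277 for H3K4me1 and 0.00924 to 0.132 for H3K4me3. Between LPS conditions it was 0.0988 to 0.284, 0.280 to 0.363 and 0.248 to 0.344, so lists with the same number deviated together there. With a replicate block, the difference in H3K27ac peaks per list was again 77846, with an exact p of 0.04 over 25 arrangements, and gains and losses were the same by construction. No other call on peaks per list changed under the block.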

Other observations

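The test of the H3K27ac ratio in lists of equal length, the use of equal length and of tied scores in reading the H3K4me3 test, the ratio without untreated replicate 1 and at 50% overlap, the weighing of the H3K27ac ratios against their SD, the ratios of H3K4me1 gains per time point, the set of regions in all 8 LPS lists and the 500 kb windows were chosen only after the results were seen. Of 3731 windows of 500 kb, 139 held 5 or more of the 2762 H3K27ac regions called in all 8 LPS lists and neither untreated list. Neighbouring regions can be pieces of 1 broad domain, so these counts are given without a test. The window with the most lay on chromosome 18 from 5500001 to 6000000 and held 30 of its 137 H3K27ac regions. Windows on chromosome 10 from 13500001 to 14000000, chromosome 13 from 20500001 to 21000000 and chromosome 16 from 24000001 to 24500000 held 15 each. Regions called in both untreated lists and no LPS list filled 35 such windows, with 23 of 68 regions on chromosome 8 from 58500001 to 59000000. A window on chromosome X from 13000001 to 13500000 held 21 of 73, beside the low share of chromosome X in the LPS replicate 2 lists of H3K27ac (0.452% to 0.678% of peaks, against 1.26% to 2.61% in the other lists).

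Among the 2762 regions, 858 (31.1%) had H3K4me1 in both untreated lists and 1554 (56.3%) in neither. Of the latter, 13 had H3K4me1 in all 8 LPS lists and 124 in 6 or more. H3K4me1 was in none of its 10 lists at 337 (12.2%) of the 2762 regions, against 99 (0.424%) of the 23342 regions with H3K27ac in all 10 lists. H3K4me3 was called in both untreated lists at 75 (2.72%) of the 2762 regions and at 59.4% of those with H3K27ac in all 10 lists.

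H3K27ac gains outnumbered losses 2.94 times in the deposited lists at an overlap of 1 bp, and 1.05 times at an overlap of 50%. At equal covered bases gains were 2.55 times the losses, with an SD of 0.970 over time points. This cannot decide on unequal covered bases as a cause, because the reduction left unequal peak numbers. LPS replicate 2 then held 177377 peaks on average and the untreated lists 44491. The untreated replicate 2 library stays open, because without it the ratio was 1.86 with an SD of 1.02, though without untreated replicate 1 it was lower still at 1.31, so the fall is not particular to replicate 2; so does the number of peaks per list, because at equal length the ratio was 0.496 while the LPS replicate 2 lists then covered 125 Mb and the untreated lists 225 Mb. Acetylation of new regions under LPS may contribute, but at equal covered bases gains exceeded the highest other call pattern at only 2 of 4 time points, and in those lists the peak numbers were unequal as given above. The direction of the imbalance therefore cannot be told apart from the different shapes of the lists.

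H3K4me3 gains were 5.77 times as numerous at 4 h as at 30 min. Longer LPS replicate 1 lists at later times stay open as a candidate explanation: the ratio of 0.164 at equal covered bases decides nothing, since that reduction falls among tied scores in untreated replicate 2, and at equal length, where it was 4.09, the LPS replicate 1 lists still covered 44.9 Mb at 30 min and 68.1 Mb at 4 h. If H3K4me3 had been gained together with acetylation, its 4 h gains would overlap an H3K27ac gain more often than regions of the other call patterns do. They did so at 7.50%, against 7.41% for the highest other pattern, a ratio of 1.01. That pattern held only 27 regions, 2 of them with such a gain. The other patterns stood lower, at 1.20% of 1163, 1.95% of 2353 and 0.816% of 2084 regions. Since the bound set in advance used the highest pattern, this explanation stays open too.

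H3K4me1 gains were above the other call patterns at only 2 of 4 time points, which library differences alone may give. In that case H3K4me1 gains would meet H3K27ac gains no more often than the other patterns do. They did so at 16.6% on average, against 9.31% for the highest other pattern, a ratio of 1.79 with an SD of 0.632 over time points. The ratio was 1.18 at 30 min, 1.48 at 1 h, 1.80 at 2 h and 2.65 at 4 h, so only the 4 h value passed the bound of 2 set in advance for the mean. The mean did not pass it, and LPS replicate 2 lists of both marks share features such as a low share of peaks on chromosome X, so library differences common to both marks and a joint gain of both marks cannot be told apart here.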
